A study of Ginkgo biloba with 2 samples.

How the data were processed

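Small RNA was sequenced from leaves of Ginkgo biloba, a gymnosperm tree, in 1 library of normal green leaves and 1 library of yellow leaves of a gold-coloured mutant. The labels' protocols describe leaves of both kinds taken from an adult tree between May and July of 2015 and 2016. They call the mutant leaves striped in yellow and green, while the sample label calls them yellow, so the yellow library here is the library of that label and may hold green tissue. They name a commercial plant RNA kit and standard Illumina library preparation, and their extraction text speaks of RNA of cambium although both samples carry the tissue label leaf. Whether leaves of several branches or years were pooled in a library is not given in the sources used here.

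A count table and a target table were used. The count table holds read counts per miRNA name as deposited by the authors, with 1 column per library. Per the file headers these are raw read counts, and the values were whole numbers from 0 upward with different totals in the libraries. Bowtie, a short-read aligner, is named in the submitters' processing notes, with no version. The genome build, the miRBase release, the tool that predicted the numbered miRNAs and the counting rule are not given in the sources used here. The table lists 467 names, of which 252 carry miRBase names from other plant species (the prefix gives the species, such as ath for Arabidopsis thaliana) in 61 numbered families, and 215 carry only a number given by the authors (novel_1 and so on, called numbered names here). The target table lists predicted target genes as deposited by the authors, each with the miRNA names predicted to bind it and the description of its best protein match. The prediction tool is not given in the sources used here. Gene positions and miRNA sequences were not analysed here, since no genome was used.

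Several names of 1 family can count the same reads. Among the 306 names with at least 20 reads, 15 sets with equal counts in both libraries held 32 names. In 12 of the sets the names were of 1 family, and 3 sets with few reads joined unrelated or numbered names, where equal counts can arise by chance. Further names of 1 family differed by a few reads. The column total is therefore a sum over names and exceeds the number of distinct reads, and names of 1 family are not independent measurements. Names with equal counts are given together.

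Counts were scaled to the column total and expressed as CPM, computed here. The ratio of yellow over green was formed for each name. Its 95% interval is the exact (Clopper-Pearson) binomial interval of the yellow share of the name's reads, converted to a ratio. With 1 library per leaf type there is no replicate spread, so no p-value between leaf types was computed. The intervals cover counting error only, compare these 2 libraries and do not compare the leaf types. Small RNA reads without molecular identifiers are not independent molecules, so the counting error itself is a lower limit. A name was called higher or lower by a rule of size: at least 20 reads in both libraries together, a ratio of at least 2 in either direction, and an interval that leaves out 1. Where 1 library had 0 reads, the ratio was computed against a floor of 3 counts in that library. This bound takes the reads of the other library as exact, and the lower bound of the counting interval is given beside it. The floor was 1.44 CPM in the green and 1.07 CPM in the yellow library. The total of the table was 2084893 reads in the green and 2793966 in the yellow library.

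The 11 lists of miRNA families, grouped by the target genes or processes they are known for, were fixed before the data were examined, as were the size rule, the target keyword groups, most of the other settings and the rule for named miRNAs. That rule took the 5 most abundant names of each library, the 8 highest and 8 lowest ratios among called names with reads in both libraries, up to 3 names per direction with 0 reads in 1 library, the 2 most-read names of each list, and up to 3 predicted targets of called miRNAs per keyword group. For each list the median log2 ratio was set against 10000 random lists of the same size drawn within 5 abundance bins, and its percentile is given as a description of these libraries. The lists were age and phase change, auxin signalling, leaf polarity and growth, GRAS and nuclear factor Y, MYB and flavonoid regulators, copper proteins and laccases, nutrient stress, small RNA pathway genes, NBS-LRR disease resistance, families described in gymnosperms, and the numbered names. No miRNA marks 1 leaf cell type alone, so no cell type list was fixed. Predicted targets were sorted into 11 groups by keywords at the start of a word in the protein description. The share of a group's miRNA-target pairs that belonged to called miRNAs was set against 10000 random sets of as many miRNAs.

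Alternatives were edgeR 4.0.16 TMM factors, DESeq2 1.42.0 median-of-ratios size factors, the total without the top miRNA, other read minimums (none, 100), other fold limits (1.5, 4), equal counts taken once, lists without their most-read member, and a pseudocount of 1. Chosen after the data were seen were 1 name per family, random target sets that kept families adjacent, and target groups under the other scalings. In the adjacent sets the names of a family took neighbouring places in a fixed sequence of calls. Neighbouring places could hold different calls, so a family was not always called together. List sums carry no interval, since names that count the same reads would make it too narrow. edgeR and DESeq2 were used for scaling only. Against the total, these scalings moved every log2 ratio up by 0.47 (TMM), 0.42 (median of ratios) and 0.27 (total without the top miRNA). The size rule was tested on simulated data: 20 pairs of Poisson libraries with the abundances and totals of these data, in which 200 of 467 names were changed. Among names with at least 20 simulated reads, the rule called 77.3% of those changed 3-fold and 99.4% of those changed 8-fold in the right direction. Names under that minimum cannot be called and were left out. Of unchanged names with enough reads 14.2% were called. Shares were rescaled to the total after the change, so the simulated ratio of unchanged names could differ from 1. Of the intervals of unchanged names, 95.7% covered the simulated ratio of shares. Analyses ran in Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1, and in R 4.3.3.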

Results

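The deposited data hold the miRNA counts of 2 leaf libraries of Ginkgo biloba, 1 from normal green leaves and 1 from yellow mutant leaves, and a table of predicted miRNA targets. The green library totalled 2084893 reads over all miRNA names and the yellow library 2793966. With 1 library per leaf type, the differences below have no replicate check, and every interval is a 95% exact interval that covers counting error only.

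The first question was which miRNAs make up the leaf pool. A small number of names held most of the summed reads in both libraries. Shares are of the column total, in which some reads count under several names. They are not shares of distinct reads, and their intervals take that total as if its reads were distinct. The most abundant was novel_1, a miRNA with only a number from the authors, with 23.5% (23.5 to 23.6) of the reads in green and 36.4% (36.3 to 36.4) in yellow leaves. It was followed by novel_12, with 17.9% (17.8 to 17.9) in green and 9.68% (9.64 to 9.71) in yellow leaves. novel_189 held 5.75% in green and 3.82% in yellow leaves. The 5 most abundant names together held 56.3% of the green and 58.0% of the yellow reads. Besides these, gma-miR166u and ath-miR166a-3p were among the first 5 in green leaves, and novel_14 and ath-miR396b-5p in yellow leaves. The numbered names of this kind together held 65.0% of the green and 68.3% of the yellow reads.

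Among the conserved families, miR166 and miR396 dominated. miR166, which targets the HD-ZIP III transcription factors that set leaf polarity, held 20.8% of the green and 14.3% of the yellow reads. miR396, known for restraining growth-regulating factors, held 10.4% in green and 14.4% in yellow leaves. The miR159 family, which targets GAMYB-type MYB proteins, held 1.26% in green and 1.96% in yellow leaves. These family shares sum names that can count the same reads. They also sum names of both hairpin arms, such as ath-miR396b-5p and ath-miR396b-3p, so the known role need not hold for every read. Reads were found for 429 names in green and 427 in yellow leaves, and 389 names had reads in both. Of the 40 names found in green leaves alone, the most-read had 9 reads, and of the 38 found in yellow leaves alone it had 52.

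**Figure D1:**
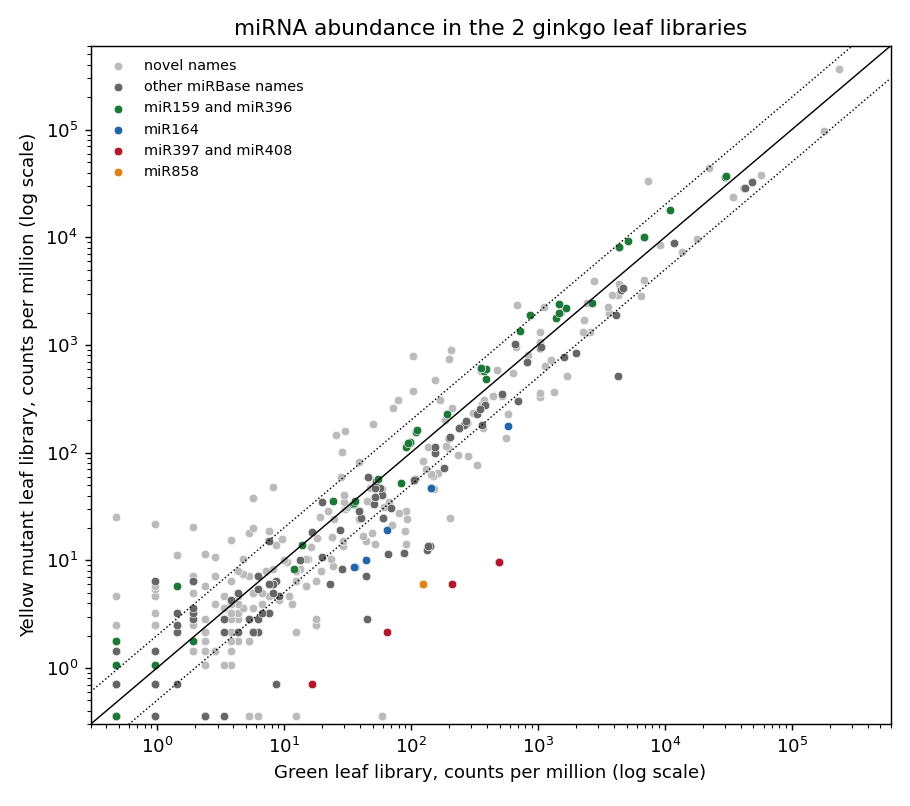
CPM of each miRNA name in the green (x axis) and yellow mutant (y axis) leaf library, both on log scales, for the 389 names with reads in both. The solid line marks equal values and the dotted lines a 2-fold difference. The miR397, miR408 and miR858 names lie far below the lower dotted line, and the 7 miR164 names with at least 20 reads lie below it too.

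The main comparison asked which miRNAs differed between yellow mutant and green leaves. The lowest conserved miRNAs in the yellow library were miR408, miR397 and miR858, which target blue copper proteins, laccases and MYB transcription factors, respectively. miR164, which targets NAC transcription factors, was also lower under every name that had enough reads. When scaled by the total, 32 of 37 higher names and 39 of 76 lower names were numbered names. With TMM 42 of 64 higher names were, and 142 of all 306 names with at least 20 reads are miRBase names. Of 306 names with at least 20 reads, 76 were at least 2-fold lower and 37 at least 2-fold higher in yellow leaves by the size rule. This split depended on the scaling. The median log2 ratio over the 306 names was -0.43 when scaled by the total and -0.01 by median of ratios, so ratios scaled by the total are read against that shift. With median-of-ratios scaling 54 names were lower and 60 higher, and with TMM scaling 50 were lower and 64 higher. Of the 76 lower names, 50 were lower under each of the 4 scalings tried. The 3 other scalings moved every ratio up by a common factor, so a name higher by the total could not lose its call.

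The miR408 names were lower by a large margin. ppt-miR408b stood at 495 CPM in green and 9.66 CPM in yellow leaves, 51.2-fold lower (interval 35 to 78.1). The names ath-miR408-3p, bra-miR408-5p and gma-miR408d had equal counts, 1029 reads in green and 27 in yellow leaves, and were 51.1-fold lower (34.9 to 77.9). osa-miR408-3p was 30.2-fold lower (13.5 to 83.6). The laccase regulator miR397 was 34.45-fold lower as pab-miR397 (21.3 to 59.7), with 437 reads in green and 17 in yellow leaves. ath-miR397a, with 35 and 2 reads, was 23.45-fold lower (6.025 to 201), and atr-miR397b had 6 reads in green and 0 in yellow leaves, at least 2.68-fold lower against the floor of 3 counts. With the counting error of both libraries the lower bound was 1.58-fold. miR858 was 20.6-fold lower as ath-miR858a (12.6 to 35.9). The names of miR397, miR408 and miR858 with at least 20 reads were lower under each of the 4 scalings.

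In the list of copper-protein and laccase miRNAs, 7 of 9 members with at least 20 reads were lower and none was higher. The list's summed ratio was 0.02465, in which reads listed under several miR408 names count several times, and its median log2 ratio was -5.11. No random list of the same size and abundance had a median as low, and the central 95% of random lists ran from -1.25 to 0.63. The random lists drew names 1 by 1, while several members count the same reads, so this band can be too narrow. With 1 name per family the list held 3 members, and its median of -5.11 stood at percentile 0.14. Of the 9 members, the 2 not called were names of miR398, the regulator of copper/zinc superoxide dismutase. ppe-miR398b had 14 reads in green and 9 in yellow leaves, and ath-miR398b-3p had 13 and 15. Their intervals included 1, and at these counts a 2-fold difference in miR398 was not detectable. The ratio of ath-miR398b-3p was 0.861 scaled by the total and 1.15 by median of ratios. That of ppe-miR398b was 0.480 by the total and 0.643 by median of ratios, and stayed below 1 under each scaling.

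**Figure D2:**
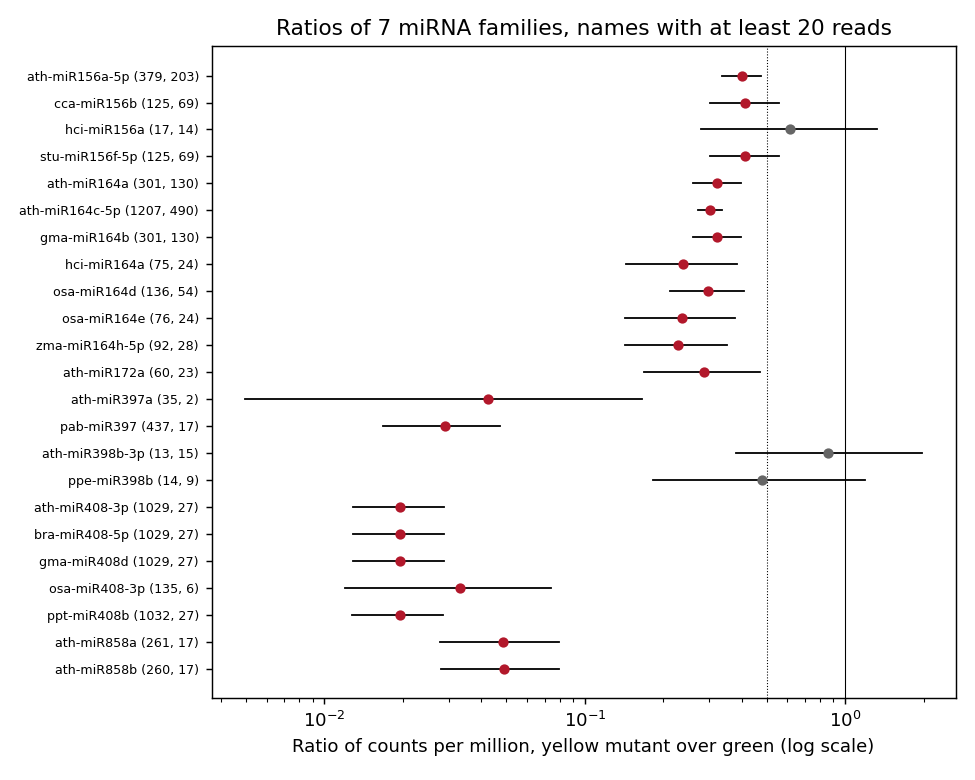
Ratio of CPM, yellow mutant over green, on a log scale, for the 23 names with at least 20 reads in 7 families. Points are ratios, bars the 95% exact intervals for counting error, brackets the reads in green and yellow leaves, and red points the 20 names called lower when scaled by the total. The intervals of the miR408 names lie below those of the miR164 names.

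In the list of leaf polarity, growth and shape, 10 of 55 members were lower and 1 was higher when scaled by the total. With TMM 7 were lower and 12 higher, with median of ratios 7 and 9, and without the top miRNA 7 and 7. All 7 miR164 names with at least 20 reads were lower, by 3.10-fold to 4.40-fold, and were lower under each scaling. The most-read of them, ath-miR164c-5p, named here after its values were seen, was 3.30-fold lower (2.97 to 3.67). The other 3 lower members were names of miR319, which targets TCP transcription factors and also stands in the MYB list. mtr-miR319a-3p was 2.18-fold lower (2.11 to 2.26), and none of the miR319 names was called under the other 3 scalings. The higher member was ppe-miR396a, with a ratio of 2.17 (2.06 to 2.29). Of the 20 miR396 names, 18 had a ratio above 1 scaled by the total and 19 under the other scalings, with 8 called higher by median of ratios. The most-read miR166 names, gma-miR166u and ath-miR166a-3p, had ratios of 0.673 (0.667 to 0.6795) and 0.673 (0.666 to 0.679).

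The list of MYB and flavonoid regulators was divided. 5 of its 27 members were lower (2 names of miR858 and 3 of miR319) and none was higher when scaled by the total. With TMM and with median of ratios 2 were lower and 4 were higher, all 4 of them names of miR159, and without the top miRNA 2 were lower and 1, a miR159 name, was higher. pta-miR159a, the most-read member, had a ratio of 1.81 (1.77 to 1.85), and 12 of 17 miR159 names had a ratio above 1, or 16 of 17 under the other scalings. The list's median log2 ratio was -0.03, at percentile 96.9 of random lists, while its summed ratio was 1.145, so the median and the sum differed in sign when scaled by the total. With 1 name per family, which takes the miR159 names once, the median was -0.48, at percentile 46.7. Under the other scalings the median was above 0, at 0.44 with TMM, 0.40 with median of ratios and 0.24 without the top miRNA.

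Among the age and phase change miRNAs, 4 of 7 members were lower and none was higher, and the median log2 ratio of -1.28 stood at percentile 7.82, or at -0.56 and percentile 24.1 with no minimum of reads. miR156, the repressor of SPL genes that marks juvenile growth, was 2.502-fold lower as ath-miR156a-5p (2.10 to 2.98) and 2.43-fold lower as cca-miR156b with stu-miR156f-5p (1.795 to 3.31). Its names kept a ratio below 1 under all 4 scalings but passed the 2-fold limit under neither TMM nor median of ratios. ath-miR172a, a regulator of AP2-like genes with 60 and 23 reads, was 3.50-fold lower (2.13 to 5.925), was called under each scaling, and is named here after its values were seen. ppt-miR529e, with 16 and 42 reads, had a ratio of 1.96 (1.08 to 3.73) and was called higher under the other 3 scalings.

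The other lists held few calls, and the medians of these and of the leaf polarity list stood between percentiles 15.5 (gymnosperm families) and 77.7 (nutrient stress). None of the 15 auxin-related members was called, and ath-miR167d and osa-miR167d-5p had ratios of 0.735 (0.662 to 0.816) and 0.722 (0.641 to 0.814), and 1 of the 9 miR167 names with at least 20 reads passed above 1 with TMM scaling. In the GRAS and nuclear factor Y list, 4 of 12 members were higher, all of them miR171 names with 18 reads in yellow and 2 or 4 in green leaves. 1 was lower, and it was smo-miR171b scaled by the total only, at 2.29-fold (1.74 to 3.02). Of the 4 higher names, ptc-miR171c, sly-miR171d and vvi-miR171f had equal counts. With equal counts taken once 2 of 8 members were higher, and with 1 name per family none was. htu-miR171a with osa-miR171b had a ratio of 0.746 (0.567 to 0.982), and their raw counts were equal in both libraries, so their direction depended on the scaling. None of the 5 small RNA pathway members was called, and ath-miR162a-3p and zma-miR162-3p, regulators of Dicer-like 1, had ratios of 0.903 (0.853 to 0.956) and 0.902 (0.852 to 0.9545), while 2 of the 3 miR162 names were above 1 under each other scaling. vvi-miR399i, of the phosphate starvation family, had a ratio of 1.30 (1.001 to 1.69), and ath-miR395a, of the sulfate family, 1.16 (0.468 to 3.04). pvu-miR2118 with gma-miR2118a-3p, which target disease resistance genes, had a ratio of 0.511 (0.232 to 1.09). Of the 2 gymnosperm names, pab-miR3711 was 6.16-fold lower (3.77 to 10.6), while pta-miR1314 had a ratio of 0.847 (0.7935 to 0.905) that passed above 1 under the other scalings.

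**Figure D3:**
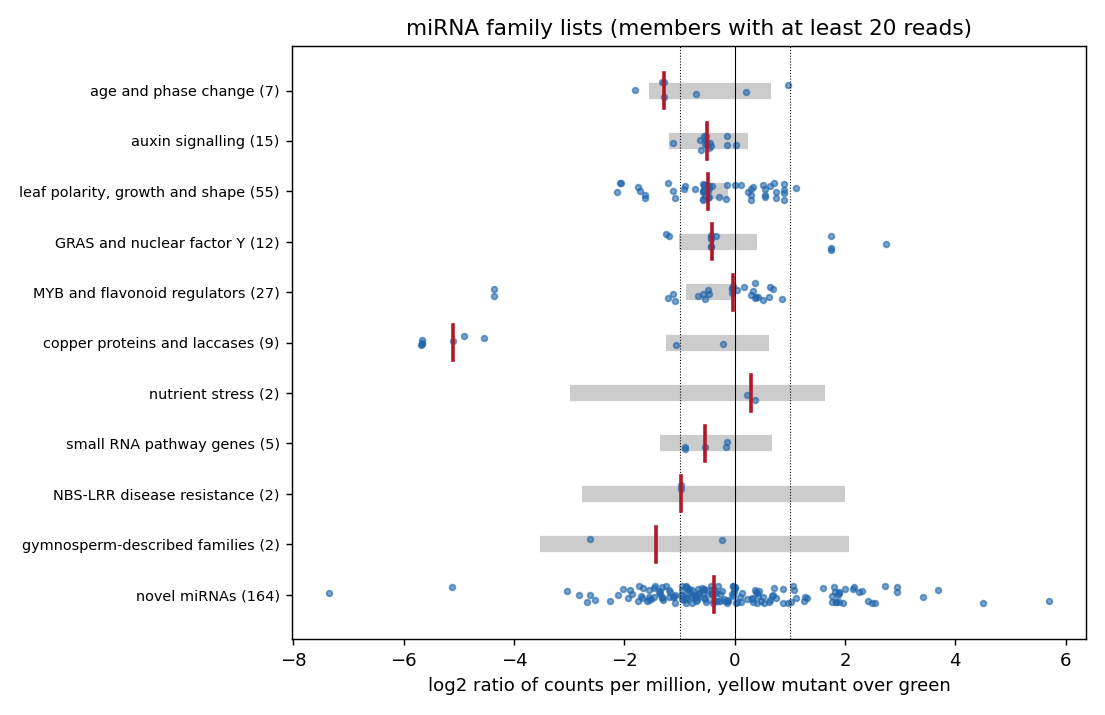
log2 ratio of CPM, yellow mutant over green, for each member with at least 20 reads (points) of the 11 miRNA lists, with the number of members in brackets. Red bars are list medians and grey bands the central 95% of 10000 random lists matched on size and abundance; the median of the copper-protein and laccase list, at -5.11, lies outside its band.

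Of the numbered names with at least 20 reads, 32 were higher, 39 lower and 93 neither, or 41 higher and 26 lower with median-of-ratios scaling. Their median log2 ratio was -0.37, at percentile 94.4, and their summed ratio 1.05, so the median and the sum differed in sign when scaled by the total. The median was 0.10 with TMM, 0.05 with median of ratios and -0.11 without the top miRNA. novel_1 had a ratio of 1.545 (1.54 to 1.551), and was called higher with TMM (2.14) and median of ratios (2.07). novel_12 had a ratio of 0.542 (0.539 to 0.545), and novel_14 one of 1.97 (1.945 to 1.99), called higher under the other 3 scalings. Among names with reads in both libraries, the highest ratios were those of novel_127, at 52.2 (9.07 to 2092) with 1 read in green and 70 in yellow leaves, novel_330, at 22.8 (6.04 to 192), and novel_137, at 10.6 (3.93 to 40.4). novel_279 had a ratio of 7.71 (2.405 to 39.4), novel_203 one of 7.69 (6.68 to 8.885), novel_312 one of 6.59 (3.62 to 13.2) and novel_116 one of 5.84 (3.51 to 10.3). lja-miR171c, the only miRBase name among the 8 highest, had a ratio of 6.72 (1.61 to 59.7). novel_136 had 52 reads in yellow and 0 in green leaves, at least 12.9-fold higher against the floor of 3 counts, and novel_320 had 20 and 0, at least 4.975-fold higher. With the counting error of both libraries their lower bounds were 10.15-fold and 3.68-fold. novel_208, with 15 and 0 reads, stood under the read minimum. In the other direction, novel_287 was 164.8-fold lower (29.0 to 6563), with 123 reads in green and 1 in yellow leaves, and novel_344 was 34.8-fold lower (5.72 to 1428). novel_166, with 9 reads in green and 0 in yellow leaves, and ptc-miR390d-3p, with 4 and 0, had too few reads for a call.

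The last comparison joined the calls to the predicted targets. The table paired 414 miRNA names with 2713 target genes, of which 2031 had a protein match. By the calls scaled by the total, lower miRNAs had 457 predicted target genes and higher miRNAs 277, among the miRNAs with at least 20 reads. These genes came from 68 lower and 24 higher names with targets, so the excess reflects the number of names called. The split of calls turned with the scaling, to 54 lower and 60 higher names with median of ratios. Target genes were counted for the total only, so whether the excess holds under the other scalings was not tested. Of the higher names, novel_320 had 72 predicted target genes with only 20 reads in all. The predicted targets of miR397 included 5 laccases, among them Gb_11065 (match Laccase-11) and Gb_14613 (match Laccase-17), both listed for pab-miR397 and ath-miR397a. Laccases are copper oxidases of lignin formation. Gb_21177, whose match was the chloroplast copper-transporting ATPase PAA2, was listed for ppt-miR408b and gma-miR408d. Of the 28 predicted targets of miR858, 16 had a protein named MYB or GAMYB as their match. In the copper protein group, 11 of 14 pairs, or 78.6%, belonged to lower miRNAs. That share stood at percentile 98.3 of random miRNA sets and at 96.4 when families were kept together, which lies inside the central 95%. The count of 11 was the same under each scaling. These pairs lay on 6 genes, the laccases listed for miR397 names and the PAA2 match listed for miR408 names. Both families were already called lower, so the share restates those calls and is no separate support. The keywords of the group missed Gb_11841 (match Basic blue protein) and Gb_33345 (match Chemocyanin). Both genes were listed for ath-miR408-3p, gma-miR408d, osa-miR408-3p and ppt-miR408b, all called lower, so the 14 pairs leave out these predicted blue copper targets of miR408.

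In the chlorophyll group, 1 of 4 pairs belonged to a lower miRNA, and 1 to a higher one under the other scalings only. Gb_38508, matching chlorophyll(ide) b reductase NOL, an enzyme of chlorophyll b breakdown, was listed for novel_130, which was 3.62-fold lower (2.496 to 5.34). None of the 3 carotenoid and terpenoid pairs and none of the 5 flavonoid and anthocyanin pairs belonged to a called miRNA when scaled by the total. Under each other scaling 1 carotenoid and terpenoid pair and 4 flavonoid and anthocyanin pairs belonged to higher miRNAs, and with a 1.5-fold limit 2 carotenoid and terpenoid pairs belonged to lower ones. Among 115 pairs of photosynthesis and chloroplast proteins, 38 belonged to lower and 10 to higher miRNAs, at percentiles 90.5 and 51.9, or 31 and 22 with median of ratios, at percentiles 96.8 and 70.5. They included Gb_03374 (match fatty acid desaturase 4), listed for novel_58, which was 3.17-fold lower (2.93 to 3.43). They also included Gb_33676 (starch branching enzyme 1) and Gb_41272 (glucose-6-phosphate 1-dehydrogenase), both listed for novel_57, whose ratio was 3.72 (3.35 to 4.15).

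Among 226 transcription factor pairs, 62 belonged to lower and 10 to higher miRNAs, at percentiles 64.8 and 10.04, or 40 and 20 with median of ratios, at percentiles 55.7 and 3.69. Gb_00228, matching Squamosa promoter-binding-like protein 1, was listed for novel_57, Gb_02968 (match PLT1, an AP2-like factor) for mtr-miR319a-3p and ppt-miR319a, and Gb_37444 (match ONAC010) for ppt-miR319a. In the small RNA pathway group, Gb_13708, matching Argonaute 7, which acts in trans-acting siRNA formation, was listed for novel_16. novel_16 had 15379 reads in green and 92749 in yellow leaves, a ratio of 4.50 (4.42 to 4.58). Gb_13632 (match Dicer homolog 3a) was listed for novel_35, which was 2.60-fold lower (1.38 to 5.08) and was called with neither TMM nor median of ratios. When scaled by the total, no hormone pair of 64 belonged to a higher miRNA, at percentile 0.67, and 10 belonged to lower ones, at percentile 9.6. This turned with the scaling, since 13 belonged to higher miRNAs and 2 to lower ones with median of ratios, at percentiles 71.7 and 0.40. The targets of the lower miRNAs included ethylene-responsive factors, Gb_39627 for 3 miR319 names and Gb_00125 for novel_28, all of them called when scaled by the total only. With a 1.5-fold limit, 11 hormone pairs belonged to higher miRNAs, at percentile 65.3. Disease resistance pairs belonged to lower miRNAs in 20 of 175 cases (percentile 4.15) and to higher ones in 7 (percentile 21.9). With median of ratios these were 10 and 15, at percentiles 4.41 and 13.9, and with a 1.5-fold limit 81 pairs belonged to lower miRNAs, at percentile 87.1. Gb_16703 (match TMV resistance protein N) was listed for novel_64, Gb_25572 (an LRR receptor-like kinase) for 2 miR319 names and Gb_34153 (another such kinase) for novel_46. F-box pairs belonged to lower miRNAs in 2 of 38 cases, Gb_06038 for novel_102 and Gb_01350 for osa-miR164e, and to a higher one in 1, Gb_36611 for novel_150. novel_102 was called with neither TMM nor median of ratios, which left 1 lower pair under each. Both with a 1.5-fold limit and with median of ratios, 26 F-box pairs belonged to higher miRNAs, at percentiles 99.75 and 99.5. The random sets for these percentiles drew names 1 by 1, while names of 1 family can count the same reads and be called together. The 38 pairs lay on 18 genes. Families were kept adjacent for the main calls only, so no conclusion is drawn from these percentiles. None of the 10 senescence and autophagy pairs belonged to a called miRNA, and 1 belonged to a lower one with a 1.5-fold limit. These are predictions, and no transcript level of any target was measured.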

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

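With 1 library per leaf type, depth sets only the counting error, and no setting below stands in for replicates. No paired analysis was possible because each leaf type has 1 library. The count of higher names was 37 and moved to 64 with TMM scaling, 60 with median-of-ratios scaling, 19 with a minimum of 100 reads and 16 with a 4-fold limit. The count of lower names was 76 and moved to 50 with TMM scaling and 32 with a 4-fold limit. The median log2 ratio of all names was -0.43 and became 0.03 with TMM, -0.01 with median of ratios and -0.17 without the top miRNA. The share of lower among called names was 67.3% by the total, 56.1% without the top miRNA, 47.4% by median of ratios and 43.9% by TMM, and this follows by construction from the common shift of all ratios. The number of lists outside the central 95% of random lists was 1 and became 2 with no minimum of reads, where the MYB list was at percentile 98.3, and 2 with 1 name per family (chosen after the data were seen), where the numbered names were at percentile 98.6 and the MYB list at 46.7. Scaling cannot change these percentiles. Under the settings that can, the copper list stayed outside, its highest percentile being 0.14 with 1 name per family. Target groups outside the central 95%, counted per direction, fell from 2 to 1 with each target taken once (hormone), 1 with a 1.5-fold limit (F-box, higher, 68.4% of pairs) and 1 with families kept adjacent (hormone, higher, percentile 0.94). Under the scalings, added after the data were seen, it was 4 with TMM (copper lower, hormone lower, F-box higher and transcription factors higher), 3 with median of ratios and 2 without the top miRNA. Families were kept adjacent for the main calls only, and even there names of 1 family could draw different calls. The counts under the scalings and the 1.5-fold limit treat names of 1 family as independent. Of 308 settings of 77 named miRNAs, 98 moved beyond the counting interval and 210 did not; the shifts are too small to turn a called direction, so this says nothing of its stability. Of 87 settings of the 11 list medians, 47 moved by 0.1 or more. The number of detected names stayed within 1.5 times under its 2 alternatives. A ratio from the authors' own normalized values was not run, since the table used holds counts only.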

Other observations

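The tests on equal counts, unlisted names and the miR397, miR408 and miR858 families were chosen after the values were seen, while those on known target classes and on the overlap of the targets of miR1511, miR4995, miR5139 and miR8155 were written before their result was seen. A group of miRBase names outside every fixed list stood apart in the yellow library. Of 13 such names with at least 20 reads, 12 were lower, 10 of them under all 4 scalings. ppt-miR894 had 8878 reads in green and 1427 in yellow leaves, 8.34-fold lower. ath-miR8175 was 15.75-fold lower, with 94 and 8 reads, and rgl-miR5139, gma-miR4995, ppe-miR1511-3p and cpa-miR8155 were 10.4-fold, 10.3-fold, 9.98-fold and 10.8-fold lower. vvi-miR2950-5p was the exception, with 42 reads in green and 97 in yellow leaves, a ratio of 1.72 by the total, and was called higher under the other 3 scalings (2.38 with TMM).

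The predicted targets held the protein class that a conserved family is known for in 18 of the 23 families searched, against a median of 2 and a highest of 9 in 10000 random pairings of classes with families. The 5 exceptions were miR162, miR168, miR172, miR396 and miR398. Some had few chances to show the class: miR398 had 1 predicted target, miR168 had 3, and miR162 had 13, of which 7 had a protein match. miR172 had 58, of which 50 had a match. None of the 110 predicted targets of miR396, of which 85 had a protein match, had a growth-regulating factor as its match. miRNAs with fewer than 20 reads supplied 45.15% of all 4625 miRNA-target pairs. The name with the most predicted targets, ath-miR5658, had 138 targets and 2 reads.

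For the lower miR397, miR408 and miR858 names, 2 technical explanations were examined. The 4 scalings differ by a fixed log2 shift of at most 0.47, too small for a total that novel_1 dominates to account for these ratios. The highest upper counting bound of their ratios over the 4 scalings was 0.229, which stays under 0.5. These families were chosen after their low ratios were seen, so that outcome was set in advance and is no separate test. Exactly the same reads under all 3 families is argued against by the green reads of their most-read names, 1032, 437 and 261, since the lowest lower counting bound of the ratio between 2 of them was 1.43. Sharing of part of the reads stays open: the highest Jaccard index of predicted targets between families was 0, against 0.312 for ath-miR408-3p with gma-miR408d, but ath-miR408-3p and bra-miR408-5p, also with equal counts, shared no target either. A difference between the leaf types, which the design names, cannot be told apart from a difference between 2 single libraries, because there was 1 library per leaf type.

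For the 12 lower unlisted names, the highest median log2 ratio over the 4 scalings was -2.72. The scalings differ by a fixed log2 shift of at most 0.47, which is small beside that median. These names were chosen because they were lower, so that outcome was set in advance. It is no separate test of a scaling shift common to all names, and no conclusion is drawn from it. For smo-miR1083 and ptc-miR6478, the 2 of the 12 that were not lower in all 4 scalings, the highest ratio was 0.687. No value decides between the scalings. Whether miR1511, miR4995, miR5139 and miR8155, with 281 to 296 reads in green and 35 to 38 in yellow leaves, are one pool of reads under 4 names stays open. rgl-miR5139 and cpa-miR8155 shared 16 of 25 predicted targets, a Jaccard index of 0.64 and the highest of the 6 pairs, but gma-miR4995, with 2 predicted targets, shared none with the others. Fragments of abundant structural RNA in differing amounts may also lie behind such names, which was not tested because read sequences and lengths were not analysed here, and a difference between the leaf types stays open as untested.

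Names of opposite hairpin arms had equal counts in 2 cases. bra-miR408-5p and ath-miR408-3p each had 1029 and 27 reads, and zma-miR396g-3p and ath-miR396a-5p each had 9166 and 22731. Counting per hairpin is argued against by ath-miR166a-3p, whose reads were at least 1511 times those of ath-miR166a-5p in both libraries. The pairs shared 0 of 11 and 1 of 24 predicted targets, the higher Jaccard index being 0.0417, which is consistent with reads of 1 mature sequence being counted under a name with another sequence, for example through a match on the opposite strand. No biological explanation was tested.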
